A study of Homo sapiens with 6 samples.

How the data were processed

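Gene expression was measured in SKOV3 cells 24 h after transfection with a miR21 precursor at 5 nM or a negative control precursor, with 3 arrays per group. Per the labels' protocols, total RNA was amplified, labelled with biotin and hybridised to U133 Plus 2.0 arrays. Per the submitters' processing notes, MAS5 made the values; its version and settings are not given in the sources used here. The deposited values are linear intensity signals per probe set, all above 0, and the mean of each array after trimming 2% at both ends is 500, so the arrays were scaled to a common level before deposit. Such scaling sets the average of each array equal, and a shift shared by most genes would not show. MAS5 signals of dim probe sets are noisy on the log scale. Nothing in the labels says that the replicates came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.

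The table holds 54675 probe sets, of which 62 are controls. Of the other 54613, the platform annotation names 1 gene for 41091, several for 1801 and none used here for 11721. The Entrez identifier of 41037 probe sets was found in a RefSeq gene table of assembly GRCh38.p14, and 0 symbols were updated. Each gene was represented by its probe set of highest mean log2 signal, and genes below the median of all probe sets (log2 6.03, a signal of 65.5) were left out, which kept 12206 of 19775 genes. Probe sets that name several genes were not used. No pseudocount was added.

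The 2 groups were compared on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) and Benjamini-Hochberg adjustment at 0.05. Before the data were examined, 21 gene lists were fixed and 20, with at least 5 measured genes, were tested with camera at an inter-gene correlation of 0.01. Single values were compared with exact two-sided permutation tests. The lists overlap: 9 of the 58 measured miR-21 targets stand in another list too. Genes were named by a rule fixed before the data were examined: APAF1, PDCD4 and a further gene that is not reported here, then up to 12 genes per direction that passed without overlap of the groups, or else 5 per direction by smallest p, and of each list up to 4 members past the threshold or else the 2 of smallest p. List members that passed under the block were named by a further rule, up to 4 by smallest p, added after the values were seen.

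The replicate numbers come from the sample titles and were taken to pair the arrays if every pair's deviations from the group means correlated above 0.1. The correlations were 0.899, 0.638 and 0.635 for numbers 1, 2 and 3, and between -0.754 and 0.411 for arrays of different numbers. A pairing with numbers 2 and 3 crossed (0.283 and 0.411) would also have passed this rule, so the pairing rests on the titles. The planned fit has no block; the fit with the replicate number as a block is printed where it changes a call. The first principal component, with 65.2% of the variance, separated the arrays of replicate 1 from the others.

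The steps were tested on simulated data for the comparison of miR21 with control, over 12206 genes with the measured means, replicate levels and a smoothed residual spread, and 200 changed genes in each of 5 runs. The fit without the block recovered 0% of genes changed by 0.5, 1 or 2 on the log2 scale. The block fit recovered 36.5%, 88.6% and 99.7% of them and called 7.4 unchanged genes per run on average. A list of 40 genes shifted by -0.5 was called in 5 of 5 runs and an unshifted list in 0. The simulated genes vary independently, unlike those of a pathway. The recovered shares hold for the smoothed spread and cannot be read as power for measured genes, whose differences varied between replicate numbers. Over all measured genes, limma with the block called KLHL2 (log2 difference 2.12, adjusted p = 0.0446). It did not call TAGLN (-2.49, 0.113), DKK1 (-2.85, 0.115) or SLC7A2 (3.06, 0.143), chosen here after their values were seen.

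The alternatives were quantile normalization, median centring, log2 of the signal plus 16, no filter or an upper quartile filter, no variance trend, array weights, other probe set rules, camera with an estimated correlation, fry, the replicate block, and each array left out. A comparison of genes with and without a miR-21 site in the 3' UTR was planned and not run, since no transcript sequences were used here.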

Results

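The series asked how the microRNA miR-21, which its title links to stromal exosomes, to taxol resistance and to the apoptosis gene APAF1, alters gene expression in ovarian cancer cells. SKOV3, an established human ovarian cancer cell line, was transfected for 24 h with a miR21 precursor at 5 nM (3 arrays) or with a negative control precursor (3 arrays). Each of the 6 samples was read on a whole-transcriptome oligonucleotide array with 54675 probe sets. The replicate numbers 1 to 3 occur in both groups, and arrays of the same number deviated together from their group means. No untransfected cells were analysed here, so each difference is that between the 2 precursors. The number of arrays limits the precision of every value.

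KLHL2, which encodes a substrate adaptor of a cullin ubiquitin ligase, was 4.33-fold higher with miR21 (log2 difference 2.12, SE 0.39). SNRPC, a spliceosome component, was 3.04-fold higher, SPRING1, a regulator of sterol-dependent transcription, was 2.62-fold higher, and the G protein subunit gene GNA13 differed by 1.59 on the log2 scale. On the lower side stood USP30, a mitochondrial deubiquitinase gene (log2 difference -1.43), the neuropeptide receptor gene NPFFR2 (-2.24), the growth factor gene PTN (-1.25), TPRG1L (-1.17) and CCNG1 (-1.18). RTCA, an RNA terminal phosphate cyclase gene, was 2.82-fold higher. All of these 10 genes had values that did not overlap between the groups, and all are given as values, since none passed the test.

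Across 12206 tested genes, limma called 0 at an adjusted p under 0.05. It held 298 genes at an unadjusted p under 0.05 (144 higher, 154 lower). Chance would give 610.3 such genes only if arrays of a replicate number shared no level. In the simulated data, which held such levels, the same fit gave an unadjusted p under 0.05 for 0.005% of unchanged genes. So 298 cannot be read as fewer than chance gives. The groups did not overlap for 812 genes, or 6.65% of those tested. The 10% that chance gives also holds only for arrays without such shared levels, so the 2 shares cannot be compared. With the replicate number as a block, limma called 4 genes, all higher with miR21: KLHL2, SNRPC, SPRING1 and the Wnt receptor gene FZD5 (log2 difference 1.78, SE 0.17), each at an adjusted p of 0.0446. At an unadjusted p under 0.05 the block fit held 2451 genes, 1198 higher and 1253 lower. FZD5 lies outside the rule for named genes and was chosen after its values were seen. Another probe set of SPRING1 differed by -0.20, and another of USP30 by 0.44, so the direction of these genes depends on the probe set.

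**Figure D1:**
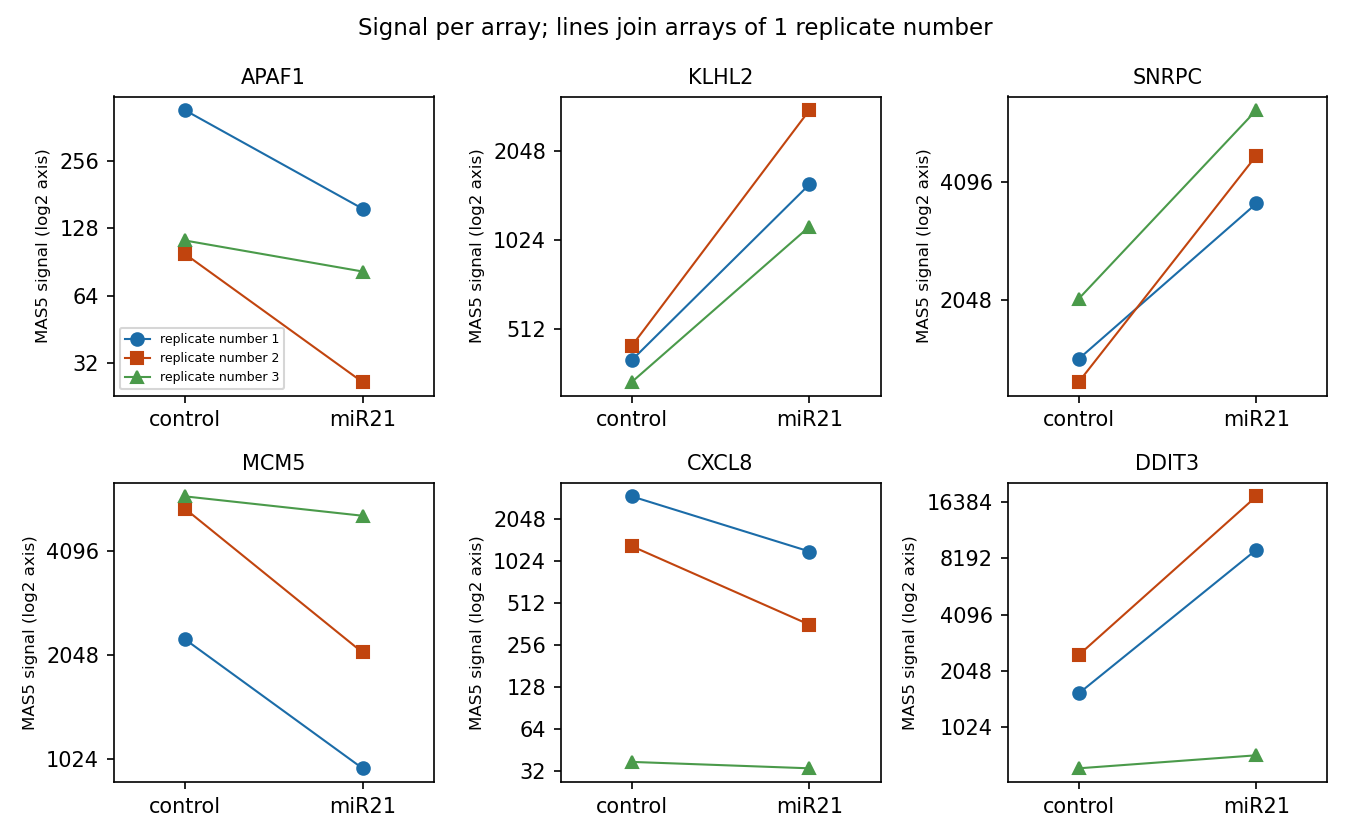
MAS5 signal (log2 axis) of 6 genes on each array, control at left and miR21 at right, with a line joining the 2 arrays of each replicate number. KLHL2 and SNRPC were higher with miR21 in all 3 numbers, while MCM5, CXCL8 and DDIT3, chosen after their values were seen, differed mainly in numbers 1 and 2. The log2 differences of DDIT3 were 2.55, 2.82 and 0.23. CXCL8 was already dim in number 3, at 37.0 (control) and 33.3 (miR21), against 2951 and 1298 on control arrays 1 and 2. A fall there could hardly show.

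The replicate numbers differed in how much they showed. Across the 12206 genes, the miR21 minus control differences of numbers 1 and 2 correlated with r = 0.696, those of numbers 1 and 3 with r = 0.159 and those of numbers 2 and 3 with r = 0.0764. Genes are not independent replicates. In number 1, 534 genes were over 1 log2 unit higher and 718 lower. In number 2 the counts were 615 and 917, and in number 3 they were 215 and 182. Of 714 genes past 1 log2 unit in the same direction in numbers 1 and 2, 453 (63.4%) had the same sign in number 3. Over all 12206 genes the sign was the same for 57.0% in numbers 1 and 3 and for 50.8% in numbers 2 and 3. Of the 714, 31 were also past 1 log2 unit in number 3 (22 with 16 added to each signal, a check added after the data were seen). The count that chance would give was not worked out. Leaving out both arrays of a number in turn, with the block, limma called 41 genes without number 1, 0 genes (885 at an unadjusted p under 0.05) without number 2, and 4099 genes without number 3 (1996 higher, 2103 lower). These 3 fits were added after the data were seen, and each rests on 2 pairs with 1 residual degree of freedom. After shrinkage the total degrees of freedom were 24.9, 6.48 and 294, so the 3 counts cannot be compared with each other. The sample labels do not say whether the replicate numbers are separate cultures or transfections.

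**Figure D2:**
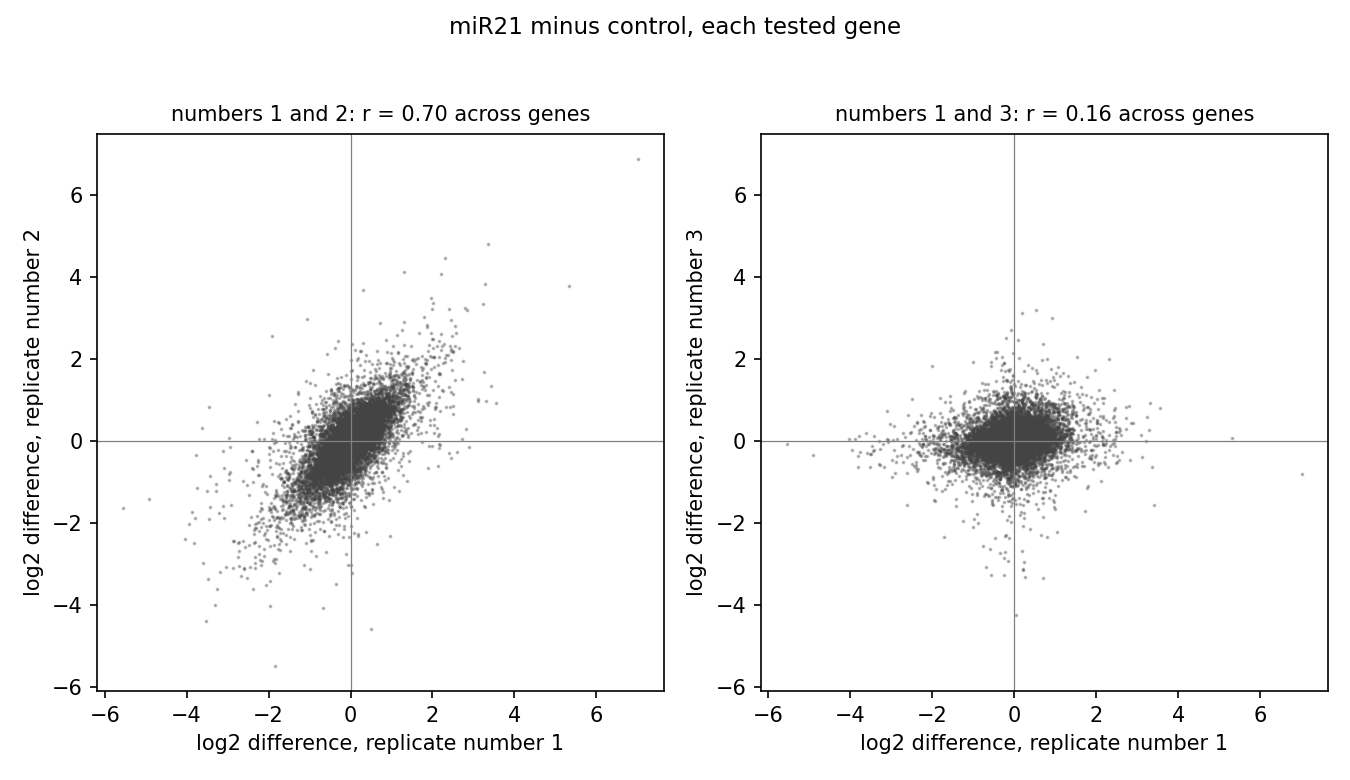
Log2 difference, miR21 minus control, of each of 12206 tested genes, with replicate number 1 on the horizontal axis and number 2 (left) or number 3 (right) on the vertical axis. The points follow a diagonal at left (r = 0.696) and scatter around the axes at right (r = 0.159).

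APAF1, the scaffold of the apoptosome, was read by 3 probe sets that did not agree. The one of highest mean signal was lower with miR21 in all 3 replicate numbers, with signals of 432, 98.3 and 113 on the control arrays and 157, 26.3 and 82.0 on the miR21 arrays, for replicate numbers 1, 2 and 3. Its log2 difference was -1.28, a signal 2.42-fold lower, and it did not pass the test in limma (SE 0.85, adjusted p = 0.9999). With the replicate block the same difference had an SE of 0.38 and an adjusted p of 0.157, and an unadjusted p of 0.0106. An exact two-sided permutation test gave p = 0.4, and 3 arrays against 3 cannot give less than 0.1. The differences within numbers 1, 2 and 3 were -1.46, -1.91 and -0.46. Another APAF1 probe set above the filter differed by -0.24, with -0.32, -0.54 and 0.14 in numbers 1, 2 and 3. The third, below the filter, differed by 0.54, with 0.23, -0.75 and 2.15, and the mean of all 3 differed by -0.32. Without 1 array at a time the difference of the first lay between -1.86 (miR21 replicate 1 left out) and -0.57 (miR21 replicate 2 left out).

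The genes of the intrinsic apoptosis pathway did not move as a group. The median log2 difference of the 29 measured members was 0.02 (camera, adjusted p = 0.900), and 0 members passed limma adjusted over the list alone, with or without the block. The members of smallest p were PMAIP1 (log2 difference 0.70) and BCL2L11 (0.69), both BH3-only genes that promote apoptosis, and neither passed. The 14 death receptor genes had a median of 0.11 (adjusted p = 0.920), with TRADD at 0.64 (another probe set 0.05, and -0.09 with the mean of probe sets) and DAXX at -0.53. Under the block, 1 of them passed adjusted over the list alone, the TRAIL receptor gene TNFRSF10B (log2 difference 0.69, adjusted p = 0.0145), whose 4 probe sets above the filter ranged from 0.03 to 0.69.

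The 24 measured genes of taxane response and multidrug transport were lower as a group, with a median of -0.37 (camera, adjusted p = 0.00934, and adjusted p = 0.515 with an estimated correlation). The microtubule destabiliser STMN1 differed by -0.72 and the transporter gene ABCC3 by 0.77, with another ABCC3 probe set at -0.18, and 0 members passed limma adjusted over the list alone. The list lost its call without control replicate 3 (adjusted p = 0.556), miR21 replicate 1 (0.537) or miR21 replicate 2 (0.0598). It kept it in camera with the block and without both arrays of number 1, 2 or 3 (adjusted p = 0.0112, 0.000613 and 0.000282). With an estimated correlation these were 0.652, 0.621 and 0.508. Its median lay at -0.66 without miR21 replicate 3 and at -0.05 without miR21 replicate 1.

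Reported targets of miR-21 were lower as a group. Of 77 listed genes, 58 were measured, with a median log2 difference of -0.32 (camera, adjusted p = 0.00252, and adjusted p = 0.270 with an estimated correlation). In all 3 replicate numbers 25 members were lower and 11 were higher. E2F1, a transcription factor of S phase entry, differed by -1.22 and the cyclin-dependent kinase gene CDK6 by -1.23, without passing limma. Under the block, 13 members passed adjusted over the list alone, 11 lower and 2 higher, against 0 without the block. They included SKP2 (-1.92), TGFBI (-1.73) and E2F1 on the lower side and JMY (0.94) on the higher side. PDCD4, a well known miR-21 target, is named alone by 1 probe set, which lay below the signal filter (log2 difference -0.21, exact permutation p = 0.7). Probe sets that name PDCD4 together with another gene were not used here, so its direction was left open. The group call was lost without control replicate 1 (median -0.16, adjusted p = 0.0998) and with the mean of all probe sets per gene (adjusted p = 0.236). It held in camera with the block and without both arrays of number 1, 2 or 3 (adjusted p = 0.00186, 0.0173 and 0.000377). With an estimated correlation these were 0.652, 0.621 and 0.352.

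Genes of the G1/S transition and DNA replication had the lowest median of the lists over all 6 arrays. The NF-kB list was lower in number 2, and both the NF-kB and interferon lists were lower without control replicate 3, miR21 replicate 1 or miR21 replicate 2. The median of 46 G1/S members was -0.91 (camera, adjusted p = 1.13e-16, and adjusted p = 0.357 with an estimated correlation), and 32 members were lower in all 3 numbers against 0 higher. The median was -1.19, -1.29 and -0.15 in numbers 1, 2 and 3, and it lay at -0.48 without miR21 replicate 1 and at -1.49 without miR21 replicate 3. Under the block 34 of the 46 fell when adjusted over the list alone, against 0 without it. Among them were the thymidylate synthase gene TYMS (-1.46), the replicative helicase gene MCM3 (-1.28), the clamp loader gene RFC2 (-0.73) and E2F1. The 47 genes of G2/M and mitosis had a median of -0.42 (adjusted p = 1.33e-06, and adjusted p = 0.401 with an estimated correlation), with ANLN at -1.41 and ASPM at -0.84 and 0 members past limma adjusted over the list alone. Their median lay at -0.65 without miR21 replicate 3 and at -0.26 without miR21 replicate 1. The 8 replication-dependent histone genes had a median of -0.51 (adjusted p = 0.00830, and adjusted p = 0.388 with an estimated correlation), with H4C8 at -0.84 and H2BC5 at -0.52. The histone median lay at -0.76 without control replicate 3 and at -0.27 without control replicate 2, and the call was lost without control replicate 1 (adjusted p = 0.0998), control replicate 2 (0.0663) or miR21 replicate 3 (0.127). Of the 5 measured DNA mismatch repair genes (median -0.26, adjusted p = 0.403), the exonuclease gene EXO1 differed by -1.55 and passed under the block adjusted over the list alone (adjusted p = 0.0281), and PMS1 differed by 0.46, with another probe set at -0.83.

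Interferon response genes were lower as a group, with a median of -0.71 over 39 members (camera, adjusted p = 1.60e-11, and adjusted p = 0.270 with an estimated correlation). The antiviral genes IFIT1 (-2.07) and SAMD9L (-1.76) did not pass limma without the block. Under the block 14 members passed adjusted over the list alone, all lower, among them OAS1 (-1.77), IFI27 (-2.34), XAF1 (-1.86) and DDX60 (-1.14). The median was -1.13 and -1.03 in numbers 1 and 2 and 0.08 in number 3, and it lay at -1.18 without control replicate 3 and at -0.47 without control replicate 2. The 21 NF-kB and inflammatory cytokine genes had a median of -0.62 (adjusted p = 0.000819, and adjusted p = 0.515 with an estimated correlation). Their median was -0.92, -1.43 and -0.13 in numbers 1, 2 and 3, and leaving out 1 array moved it from -0.62 to as far as -1.88 (control replicate 3) or -0.19 (miR21 replicate 3). TNFAIP2 differed by -1.41, and 10 members passed under the block adjusted over the list alone, 9 of them lower, among them IL6 (-1.70), TNF (-1.96), the adhesion gene ICAM1 (-1.47) and the NF-kB inhibitor gene NFKBIA (-1.54). Both lists started from a lower level in control replicate 3, where 21 of the 21 NF-kB genes and 33 of the 39 interferon genes lay below the mean of the other control arrays. The NF-kB call was lost without control replicate 1 (adjusted p = 0.0998), control replicate 2 (0.0966) or miR21 replicate 3 (0.672). It held in camera with the block and without both arrays of number 1, 2 or 3 (adjusted p = 1.09e-05, 0.000651 and 1.64e-11). With an estimated correlation these were 0.652, 0.621 and 0.347.

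Mesenchymal genes had a median of -0.34 over 18 members (camera, adjusted p = 0.00511, and adjusted p = 0.270 with an estimated correlation). SNAI2, an epithelial-mesenchymal transition factor, differed by -1.36 and the actin-binding gene TAGLN by -2.49, with another TAGLN probe set at 0.16. Under the block 5 members passed adjusted over the list alone, all lower, including SNAI2, TAGLN, TGFBI and the matrix gene THBS1 (-2.62). The mesenchymal call was lost without control replicate 1 (median -0.18, adjusted p = 0.109). It held in camera with the block and without both arrays of number 1, 2 or 3 (adjusted p = 0.000887, 0.0122 and 0.000113). With an estimated correlation these were 0.652, 0.621 and 0.352. The 24 TGF-beta response genes had a median of -0.33 (adjusted p = 0.0275, and adjusted p = 0.342 with an estimated correlation), and the call was lost with the block (adjusted p = 0.109). It was also lost with arrays centred on their median (0.0984), and without control replicate 1 (0.120), control replicate 2 (0.0966) or miR21 replicate 1 (0.0628). The TGF-beta median lay at -0.22 without control replicate 2. Its members went both ways: CCN2 differed by -1.95, and of 11 members past the block fit adjusted over the list alone 7 were lower, such as CCN1 (-1.82), and 4 higher, such as ID2 (1.24).

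ERK feedback and immediate early genes were higher as a group, with a median of 0.39 over 25 members (camera, adjusted p = 0.0178, and adjusted p = 0.629 with an estimated correlation). ETV4, a transcription factor downstream of ERK, differed by 2.00 and KLF6 by -1.38. Under the block 13 members passed adjusted over the list alone, 10 higher and 3 lower, with the phosphatase genes DUSP5 (1.52) and DUSP6 (0.92) among the former. The call was lost without control replicate 3 (adjusted p = 0.984), miR21 replicate 1 (0.687) or miR21 replicate 2 (0.202) and with the upper quartile filter (0.439). It held in camera with the block and without both arrays of number 1, 2 or 3 (adjusted p = 0.0111, 0.000962 and 0.000739). With an estimated correlation these were 0.652, 0.621 and 0.352. The ERK medians within numbers 1, 2 and 3 were 0.53, 0.52 and 0.21. The ERK median lay at -0.0065 without control replicate 3 and at 0.85 without miR21 replicate 3. Unfolded protein response genes were higher as well, with a median of 0.39 over 26 members (adjusted p = 0.00135, and adjusted p = 0.270 with an estimated correlation). That median was 0.73, 0.36 and 0.06 in numbers 1, 2 and 3, and it lay at 0.31 without miR21 replicate 2 and at 0.80 without miR21 replicate 3. The chaperone gene HSPA5 differed by 0.88 and the mTORC1 inhibitor gene DDIT4 by 1.83. Under the block 10 members passed adjusted over the list alone, 9 higher, including DDIT3 (1.87), TRIB3 (1.73) and DNAJB9 (1.14). The 21 hypoxia response genes had a median of 0.12 (adjusted p = 0.0794), with DDIT4 and NDRG1 (1.22) of smallest p. Under the block 3 of them passed adjusted over the list alone, DDIT4, VEGFA (1.08) and ADM (0.77). The list passed camera without control replicate 2 (adjusted p = 0.0144) or miR21 replicate 3 (0.0293), with arrays centred on their median (0.0302), and with the block without both arrays of number 2 (0.0207) or number 3 (0.00350). With an estimated correlation the adjusted p was 0.408 over all arrays, and 0.621 and 0.456 in these block fits.

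Cholesterol biosynthesis genes were lower, with a median of -0.63 over 19 members (camera, adjusted p = 1.62e-05, and adjusted p = 0.270 with an estimated correlation). ACAT2 differed by -1.22 and the sterol sensor gene INSIG1 by -1.03, and 0 members passed limma adjusted over the list alone. The median was -0.79 and -0.89 in numbers 1 and 2 and 0.07 in number 3, and it lay at -0.37 without miR21 replicate 2.

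The remaining lists did not pass camera. Over 23 epithelial genes the median was -0.13 and the mean 0.01, with opposite signs (adjusted p = 0.900), while ELF3 differed by -0.96 and CLDN7 by 1.42. The 15 microRNA pathway genes had a median of -0.02 (adjusted p = 0.920), with DDX6 at 0.28 and DROSHA at -0.27. The 46 cytosolic ribosomal protein genes had a median of -0.04 (adjusted p = 0.600), with RPL14 at -0.25 (another probe set 0.19) and RPS24 at -0.15. By replicate number their median was -0.05, 0.30 and -0.40, and the list passed without control replicate 1 (adjusted p = 0.0319) and miR21 replicate 2 (0.00743) with a lower median, and without control replicate 3 (0.00505) with a higher one. With the block and without both arrays of number 2 it passed with a median of -0.22 (adjusted p = 4.35e-06, and adjusted p = 0.621 with an estimated correlation). Quantile normalization and median centring also turned its sign. Markers of other cell types were mostly below the signal filter. Of 21 stromal fibroblast and adipocyte markers 7 were measured (median -0.19, adjusted p = 0.600), with COL1A2 at -0.52 (another probe set 0.28) and MMP11 at 0.38. Of 21 immune and endothelial markers 2 were measured, CD79A (-0.42) and PECAM1 (-0.44), too few to test.

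**Figure D3:**
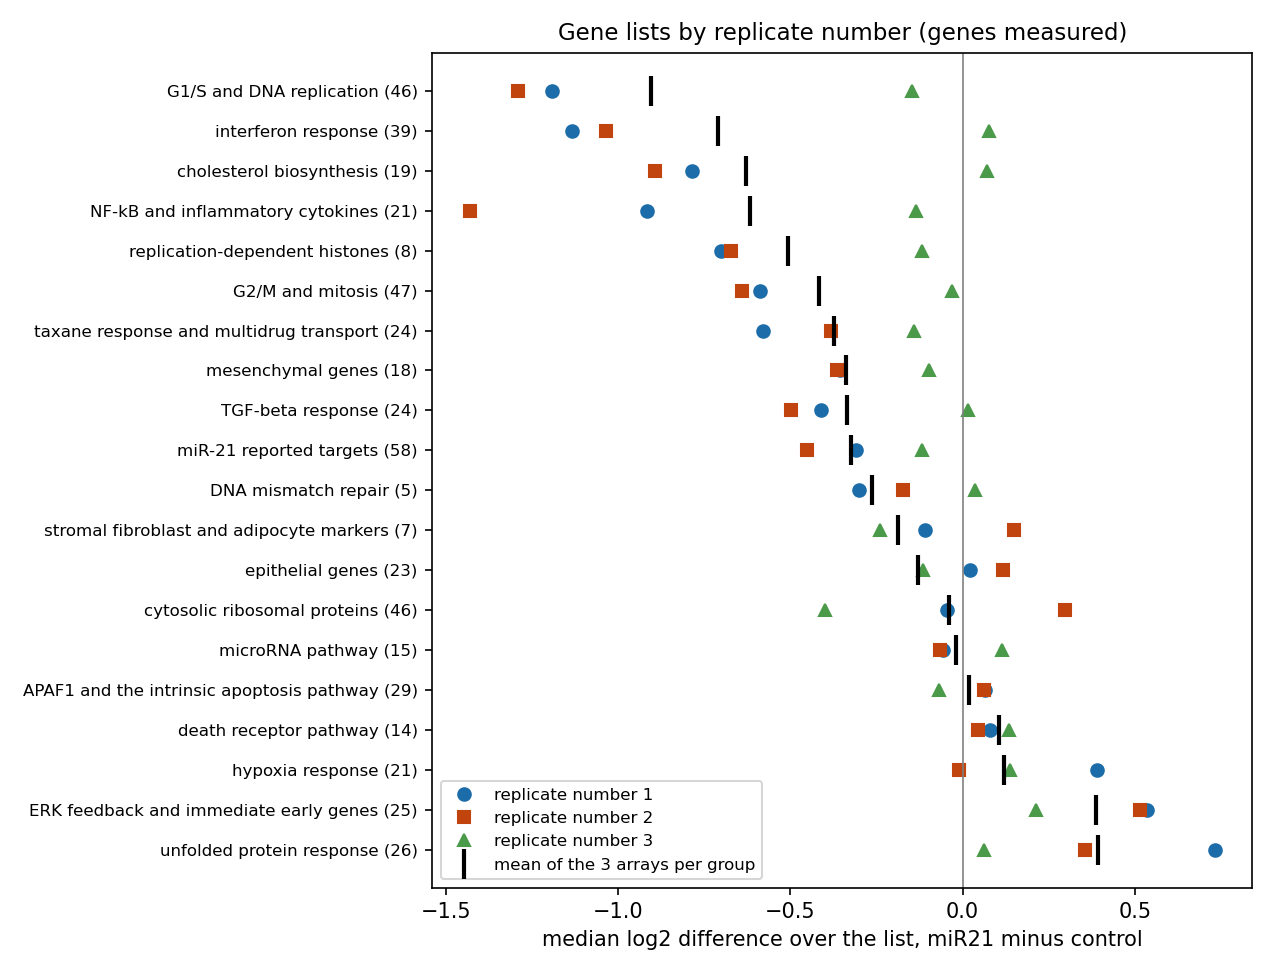
Median log2 difference, miR21 minus control, of each of 20 tested gene lists (horizontal axis), with a symbol for each replicate number, a bar for the difference of the group means, and the number of genes measured in brackets. The G1/S list has medians of -1.19 and -1.29 in numbers 1 and 2 and -0.15 in number 3.

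Of the 20 lists tested, 12 passed camera with a preset correlation of 0.01, 10 lower and 2 higher. With the block 11 passed. With an estimated correlation 0 lists passed, 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.270. That correlation was estimated from 6 arrays and, without the block, from residuals that hold the levels shared by a replicate number. With the block most lists had the same adjusted p of 0.480. It called the shifted simulated list in 5 of 5 runs, but those genes vary independently. A list that did not pass it is therefore not shown to be unchanged. With fry, which asks whether a list's genes move on balance in a single direction, 0 passed and 0 had an unadjusted p under 0.05. The interferon, G2/M, G1/S, cholesterol and unfolded protein response lists passed camera at the preset correlation without each of the 6 arrays in turn. They also passed it with the block and without both arrays of number 1, 2 or 3. So did the miR-21 target, taxane, NF-kB, mesenchymal and ERK feedback lists. The TGF-beta list did not without number 2 (adjusted p = 0.274), nor the histone list without number 2 (0.0650) or 3 (0.0537). Camera with an estimated correlation called 0 lists in these fits.

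Some array quality measures differed between the replicate numbers. The median signal of all probe sets was 125 and 117 on the control and miR21 arrays of replicate 1, and lay between 55.2 and 61.8 on the other arrays. The ratio of 3' to 5' signal of ACTB was 1.79 and 1.96 in replicate 1, 2.88 and 3.32 in replicate 2, and 1.29 and 1.36 in replicate 3. Exact permutation tests of 11 measures between the groups gave p between 0.5 and 0.9 (0.9 after Benjamini-Hochberg adjustment), with 0.1 the smallest possible. Within pairs, 4 of the 11 measures had the same sign in all 3 numbers: with miR21 the ACTB ratio and the GAPDH ratio of 3' to middle signal were higher, and the median signal and the bioB spike-in were lower. Signs of 3 pairs cannot give an exact p below 0.25.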

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

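The fits without both arrays of a number, and the lists without shared genes, were chosen after seeing the data. The count of genes past the threshold was 0 under every setting chosen before the data were examined except the replicate block, where it was 4; it was 0 without each of the 6 arrays in turn (92 to 853 genes at an unadjusted p under 0.05). Array weights left 0 genes, with 1793 at an unadjusted p under 0.05; the weights stopped short of full convergence. With the block and without both arrays of number 1, 2 or 3, the counts were 41, 0 and 4099, with 1 residual degree of freedom each, and the cause was not tested. The block removes the spread shared by arrays of a number, and the median SE went from 0.423 to 0.195. The count of lists was 0 with an estimated correlation and 0 with fry, 10 to 12 under the other settings, and 8 to 11 without 1 array. The log2 difference of APAF1, from its brightest probe set or the mean of all, kept its sign under every alternative run, from -1.86 to -0.32, and passed the threshold only with the block and without both arrays of number 3 (-1.68, adjusted p = 0.000589). The adjusted p was 0.157 to 0.9999 otherwise. Apart from these counts, the counts over single lists given with each list, the 3 genes named by rule that it called and the TGF-beta list, the block changed no call. Without genes that other lists hold, the miR-21 targets had a median of -0.30 (adjusted p = 0.00998) and the taxane list one of -0.37 (0.0178). Another scaling moved the median of all genes from -0.01 to 0.09 at most.

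Some medians and single genes changed sign, most from near 0, but ERK feedback from 0.39, TRADD from 0.64, MMP11 from 0.38, COL1A2 from -0.52, and CD79A and PECAM1 from -0.42 and -0.44. Apart from TRADD, these signs changed on leaving out 1 array, after which the groups no longer share all replicate numbers. CD79A had signals of 606 and 378 in number 1 against 79.4 to 115 elsewhere, and PECAM1 483 and 397 against 22.3 to 53.4. Within numbers 1, 2 and 3, CD79A (-0.68, -0.06 and -0.53), PECAM1 (-0.28, -0.997 and -0.04) and the ERK medians kept their sign. MMP11 did not (0.49, 0.88 and -0.24). The level of number 1 thus enters for CD79A and PECAM1, and other causes were not tested. The intrinsic apoptosis list went to -0.0078 with quantile normalization, -0.0074 with the upper quartile filter, -0.040 with the mean of probe sets, and -0.0066 and -0.074 with the block and without numbers 1 and 2. The ribosomal list went to 0.024 with quantile normalization, 0.061 with median centring and 0.124 with the block and without number 3. The microRNA pathway list went to 0.079 with median centring and 0.026 with the mean of probe sets, which also took the death receptor list to -0.00093 and TRADD to -0.088. Array weights took RPS24 to 0.019, and the hypoxia list went to -0.013 with the block and without number 1. Without 1 array the medians ran from -0.13 to 0.13 for intrinsic apoptosis, -0.13 to 0.16 for death receptors, -0.51 to 0.045 for stromal markers, -0.15 to 0.11 for epithelial genes, -0.0065 to 0.85 for ERK feedback, -0.049 to 0.35 for hypoxia and -0.20 to 0.14 for ribosomal proteins. The differences ran from -1.12 to 0.41 for CD79A, -1.62 to 0.66 for PECAM1, -0.28 to 0.025 for RPS24, -0.029 to 0.88 for MMP11, -0.49 to 0.0080 for DROSHA, -0.51 to 0.10 for RPL14 and -0.80 to 0.015 for COL1A2. The comparison by miR-21 sites was not run. Signal over background limits dim genes: an APAF1 probe set below the filter differed by 0.54.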

Other observations

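The tests on replicates 1 and 3 and the count of splits for genes were chosen only after the result was seen, and the spike-in, random-list and RNA integrity tests were widened after a first scoring, on bioB alone, without the other lists and on ACTB 3' to 5' alone, had decided them. The count of splits for lists was set before, while the ATF4-linked and chaperone lists were drawn up after the unfolded protein response genes were seen to be higher and before their own values were seen. The genes named in this paragraph were chosen after their values were seen, and none passed limma over all genes with or without the block, while SKP2 passed under the block adjusted over its list alone. S100P, a calcium-binding protein gene, had signals of 15.2, 47.4 and 31.2 on the control arrays and 1962, 5597 and 17.8 on the miR21 arrays, for numbers 1, 2 and 3. The cationic amino acid transporter gene SLC7A2 differed by 5.32, 3.79 and 0.09 on the log2 scale, and the transcription factor gene FOXQ1 by 3.22, 3.35 and -0.003. On the lower side, the Wnt inhibitor gene DKK1 differed by -3.53, -4.39 and -0.64 and the protease gene ADAMTS1 by -3.60, -2.97 and -0.28. Past 1 log2 unit in all 3 numbers were 19 higher genes, including the 4 called with the block, and 12 lower genes, among them SKP2 (-2.10, -2.63 and -1.03). With 16 added to each signal, a check added after seeing the data, 16 of the higher genes and 6 of the lower remained, so some of these differences rest on dim signals.

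Of the lists drawn up further, that of amino acid and ATF4-linked genes was higher in numbers 1 and 2. Its 32 genes, none of them in the 21 lists, had a median log2 difference of 0.83, with 1.27, 1.35 and 0.01 in numbers 1, 2 and 3, and 30 members were higher in numbers 1 and 2. Under the block 27 of the 32 passed limma adjusted over the list alone, 26 of them higher. With the block camera gave p = 1.60e-13 at the preset correlation and p = 0.237 with an estimated correlation, so a programme of such genes remains open. In a list of 21 endoplasmic reticulum chaperone genes, 9 were higher in numbers 1 and 2, and the higher of the medians was 0.040, short of the 0.2 set for a rise of folding genes as a whole, and above the 0 set to exclude it. Neither explanation was decided, and no other biological explanation was tested.

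Replicate 3 showed little of the change seen in numbers 1 and 2. Exchanged labels within number 3 would give negative correlations with the other differences, and the lower of these was 0.0764. A number with little change gives correlations near 0 under either labelling, so this decides little. With the block, the split that exchanges number 3 gave 0 genes and 12 lists, against 4 genes and 11 lists for the real labels. Noise is argued against by an SD across genes of 0.425, below the 0.664 and 0.712 of numbers 1 and 2. A low starting level may account for the inflammatory cytokine genes, whose median in control replicate 3 lay at -2.04 (log2) against the mean of the other control arrays, but not for DNA replication genes, where it was 0.54. Not every cytokine list member bears this out. IL6 (-1.79) and ICAM1 (-1.58) also started low and were still lower with miR21 in number 3, at dim signals, against a list median of -0.13. Absent miR-21 activity stays open: the median of the reported targets lay at the 0.17 percentile of 10000 random lists in number 3, but 4 of the 19 other lists also lay outside the central 95%. Of these, G1/S (percentile 0) and ERK feedback (99.5) lay on the same side as in numbers 1 and 2. Hypoxia (98.1) did so only for number 1, and ribosomal proteins (0.04) for neither. Whether these lists hold genes that move together or responded in number 3 was not tested. A weaker response of that culture or transfection was not tested.

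The arrays of replicate 1 stood apart from the rest. RNA integrity and a difference at hybridisation or scanning both stay open. Of 4 ratios of 3' to 5' or middle signal, 3 lay outside those of replicates 2 and 3 in both groups, with no tolerance set: both GAPDH ratios stood clear, with 3' to 5' at 1.07 on both arrays, while ACTB 3' to middle was barely outside (1.396 against 1.391, and 1.512 against 1.508) and ACTB 3' to 5' lay between the others. Against the mean of replicates 2 and 3, the spike-in bioB was 2.44 and 3.18 times as high in the control and miR21 arrays, while bioC was at 0.499 and 0.537 of it. The spike-ins bioD (0.470 and 0.514) and cre (0.659 and 0.679) were lower too, so each spike-in moved the same way in both groups. The smallest factor over 4 spike-ins and both groups was 1.47, short of the 1.5 set for this explanation, and no biological explanation was tested.

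The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold without the block the real split gave 0, and the highest of the others gave 0, so 10 of the 10 splits gave as many. A real count of 0 makes that outcome certain, so it decides nothing about chance. For lists the real split gave 12 and the highest of the others 11, so 1 of the 10 splits gave as many. Of the 4 splits that part all 3 pairs, fitted with the block, the real one gave 4 genes and 11 lists. The highest of the others gave 0 genes and 12 lists, and these 12 came from the split that exchanges number 3. At an unadjusted p under 0.05 another split gave 2920 genes against 298, which points to the structure of the replicate numbers.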
